A study of Homo sapiens with 16 samples.

How the data were processed

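RNA sequencing and chromatin accessibility sequencing (ATAC-seq) were done on 8 established human breast cancer cell lines: AU-565, BT-474, MCF7, MDA-MB-231, MDA-MB-361, SK-BR-3, T-47D and ZR-75-1. The labels list 16 samples, 8 of RNA and 8 of chromatin, 1 of each kind per line. The 8 RNA libraries are the subject here, and the 8 ATAC-seq libraries were not analysed here. Per the labels, the RNA libraries were made with a kit that selects poly(A) RNA and marks the strand.

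The authors deposited 1 table of gene expression in TPM (transcript abundance scaled to the same total in each library), with 60396 Ensembl gene identifiers and 1 column per RNA library. Each column summed to 1000000. The submitters' processing notes name STAR and HTSeq with the genome builds hg38 and GRCh38. Versions, the annotation release, the gene lengths behind TPM and any filter are not given in the sources used here. Gene symbols and positions were taken from the reference annotation on GRCh38.p14. A symbol was found for 56284 identifiers (93.2%), and the other 4112 were kept under their identifiers. The table held 22081 identifiers listed at 0 in every library. XIST and Y-linked genes (427 identifiers) were left out of every result. The 13 mitochondrially encoded mRNAs of the fixed list were not in the table.

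The growth notes in the labels give DMEM for BT-474, MCF7, MDA-MB-231 and MDA-MB-361, RPMI for T-47D and AU-565, and McCoy's 5A for SK-BR-3, with insulin added for T-47D. They name no medium for ZR-75-1. Medium and cell line cannot be told apart, since each line was grown in 1 medium and measured once.

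TPM holds no read depth of its own. Depth was therefore estimated from the steps between the values of each gene, which are whole multiples of 1 read for a gene of fixed length. Whole reads came out for 29574 of 29574 genes seen in at least 3 libraries, each value within 0.0001 of a whole number. Another 8741 genes seen in 1 or 2 libraries were not tested in this way. On simulated libraries 98.4% of 27710 genes came out exactly, and 99.3% of the 18087 genes with at least 100 reads summed over the libraries. The reads were used to state depth and not for any test.

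Values were compared as log2(TPM + 1). A fold on this scale understates the change of genes with low TPM. Genes with at least 1 TPM in at least 1 line were considered, which left 20443 genes, 450 of them without a symbol. The reference for a line was the median of the other 7 lines. With 1 library per line there is no estimate of spread, so no test across genes was run and no gene has a p. A gene was said to stand apart by a size rule: a difference of at least 2 on the log2 scale (4-fold), with at least 10 TPM in the line for a higher gene or in the reference for a lower gene. On a simulated line this rule recovered 100% of 50 genes changed 16-fold and 98% of 50 changed 8-fold, in either direction, and called 0 of 20243 unchanged genes. The spread of the simulated genes was assumed, not taken from replicates, and was far smaller than the size rule. The lack of false calls followed from that setting and gives no rate for the real libraries. Changes near 4-fold were not simulated.

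Before the data were examined, 35 gene lists were fixed, along with the size rule, the relations across lines, the alternatives and the rule for naming genes. The rule names, per line, the 12 genes with the largest higher and the 8 with the largest lower difference among genes standing apart, and 10 in each direction for AU-565 against SK-BR-3. Clone-based, LOC, LINC, antisense and pseudogene names and mitochondrial genes were passed over, which left 14540 nameable genes. Noncoding genes with a symbol of their own, such as H19, were kept. The rule adds 16 receptor, lineage and tumour genes in every line and up to 4 members of each list. For each list with at least 5 members considered, the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called higher at or above percentile 99.5 and lower at or below percentile 0.5. The percentile describes these libraries and is not a p, because genes of a list vary together. On a simulated line 20 of 20 lists of doubled genes were called, and 3 of 100 lists of unlinked genes.

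Similarity was Pearson's r across genes for the 28 pairs of lines, with average-linkage clustering on 1 minus r. Genes are not independent replicates, so r has no p. For 7 relations across lines, AU-565 and SK-BR-3, which cell line catalogues list as related, were averaged into 1 value. Pearson's r and Spearman's rho over the 7 values were tested by two-sided exact permutation, for which the smallest possible p is 0.000198, with Benjamini-Hochberg adjustment. No r was given where the largest gap between neighbouring values of the gene was more than 0.5 of their range. Runs of neighbouring genes were sought in windows of 15 genes in chromosome order among 17671 genes. A window was called when its median difference lay beyond the 95th percentile of the most extreme window in 1000 shuffles of gene order. On a simulated line the runs held 30 of 30 planted genes, 2 further runs were called beside the planted block, and an unchanged library gave 0 runs. The simulated genes varied independently of their neighbours, so the lack of runs followed from that setting and gives no rate for the real libraries.

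The alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, rescaling by the median of ratios over 10543 genes, the mean as reference, leaving each library out of the reference in turn, and AU-565 and SK-BR-3 averaged in references. The same averaging of MDA-MB-231 with the library labelled ZR-75-1 and the comparison of these libraries were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.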

Results

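The 8 breast cancer cell lines were each measured by 1 RNA library, so there are no replicates and every value is a single measurement without an error. The study's title names RNA and chromatin accessibility in breast cancer cells, and the comparison made here is of each line with the other 7. Estimated depth ran from 32682100 reads in genes in AU-565 to 45013900 in MDA-MB-231. A gene at 10 TPM rested on a median of 365 reads in the library with the lowest such median and 456 in that with the highest. Between 13336 genes (AU-565) and 15772 genes (MDA-MB-361) were listed at 1 TPM or more. RPL19, a ribosomal protein gene near ERBB2, was the most abundant gene in AU-565 (3.26% of all TPM), SK-BR-3 (3.18%) and BT-474 (2.62%). KRT8, a luminal keratin, led in MCF7 (2.03%), TCN1, a vitamin B12 binding protein, in MDA-MB-361 (0.584%), and ACTB in the other lines.

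The closest pairs of lines were MDA-MB-231 with the library labelled ZR-75-1 and AU-565 with SK-BR-3. The library labelled ZR-75-1 lay nearest to MDA-MB-231 (Pearson r 0.976 across genes), AU-565 nearest to SK-BR-3 (0.970), BT-474 nearest to MDA-MB-361 (0.921) and MCF7 nearest to T-47D (0.898). T-47D with BT-474 (0.898) and MCF7 with BT-474 (0.896) were almost as near. BT-474, MDA-MB-361, MCF7 and T-47D joined next, at a mean r of 0.892, then AU-565 with SK-BR-3 at 0.860, and MDA-MB-231 with the library labelled ZR-75-1 last at 0.805. MDA-MB-361 and MDA-MB-231 had the lowest r (0.786), with 2324 genes apart by the size rule. AU-565 and the library labelled ZR-75-1 had the most genes apart (2555, with r 0.800). ZR-75-1 is catalogued as a luminal line with estrogen receptor, and MDA-MB-231 as a mesenchymal line without it. The 124 genes apart between these libraries compare with a median of 1813 over the other 27 pairs (207 to 2555).

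**Figure D1:**
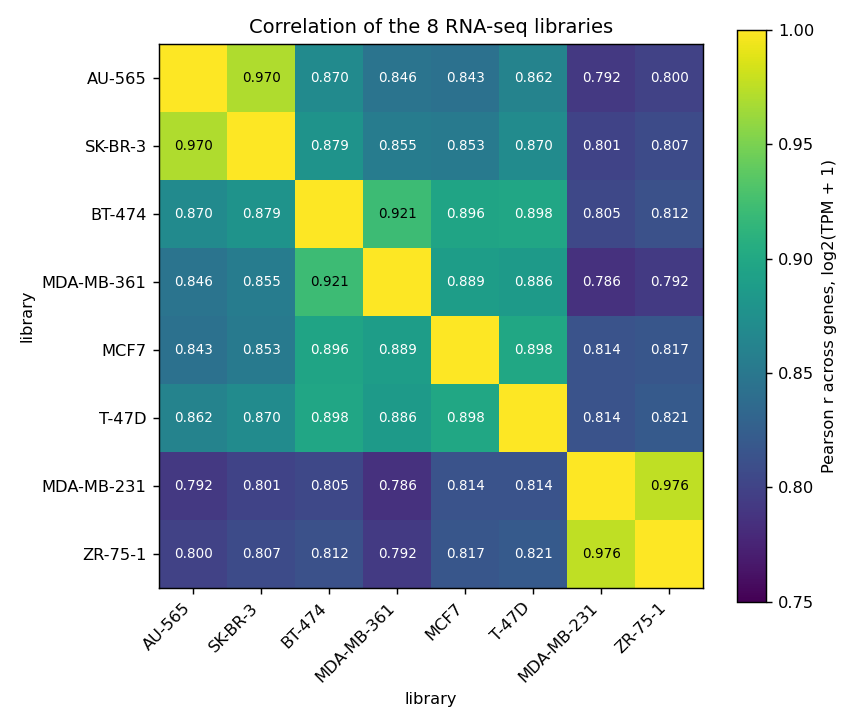
Pearson r across genes of log2(TPM + 1) for each pair of the 8 RNA libraries, 1 library per line, with colour giving r. The highest values are 0.976 for MDA-MB-231 with the library labelled ZR-75-1 and 0.970 for AU-565 with SK-BR-3.

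ERBB2, the receptor gene amplified in HER2-positive breast cancer (chromosome 17, 39688094 to 39728658), stood at 4649 TPM in AU-565, 3268 in SK-BR-3, 3153 in BT-474 and 1274 in MDA-MB-361. It stood at 139 TPM in T-47D, 60.1 in MCF7, 52.0 in MDA-MB-231 and 48.7 in the library labelled ZR-75-1. ESR1, the estrogen receptor gene (chromosome 6, 151656672 to 152129619), stood at 189 TPM in MCF7, 95.9 in T-47D, 81.8 in MDA-MB-361 and 30.5 in BT-474, and below 1 TPM in the other 4 libraries. PGR, the progesterone receptor, followed the same split, with 371 TPM in T-47D, 303 in BT-474, 166 in MCF7 and 104 in MDA-MB-361. In the library labelled ZR-75-1, ESR1 was listed at 0.511 TPM and PGR at 0.244.

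GATA3, a luminal transcription factor, stood at 1367 TPM in MCF7 and 845 in T-47D, and at 4.41 in AU-565 and 6.46 in MDA-MB-231. FOXA1, which opens chromatin for steroid receptors, stood at 250 to 625 TPM in 6 lines, against 5.66 in MDA-MB-231 and 18.4 in the library labelled ZR-75-1. CDH1, the epithelial cadherin, stood at 1500 TPM in MDA-MB-361, 726 in MCF7, 644 in BT-474 and 525 in T-47D, against 0.268 in AU-565, 0.308 in SK-BR-3, 0.756 in MDA-MB-231 and 27.7 in the library labelled ZR-75-1. VIM, an intermediate filament of mesenchymal cells, reached 3096 TPM in MDA-MB-231 and 2976 in the library labelled ZR-75-1, and ZEB1, a repressor of CDH1, reached 68.4 and 56.1. EGFR reached 343 and 487 TPM in the same libraries, against 1.99 in MCF7. AR, the androgen receptor, lay between 0.712 TPM in SK-BR-3 and 35.0 in MCF7 and MDA-MB-361.

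MYC stood at 555 TPM in the library labelled ZR-75-1 and 225 in MDA-MB-231, against 47 in MDA-MB-361. CCND1, a G1 cyclin, lay between 192 TPM in SK-BR-3 and T-47D and 700 in MDA-MB-231. CDKN2A, a brake on the cyclin D kinases, was listed at 0.137 TPM in MDA-MB-231, 0.785 in the library labelled ZR-75-1 and 4.23 in MCF7, against 83.7 in T-47D. CASP3, an apoptosis protease, was lowest in MCF7 (11 TPM), TP53 in MDA-MB-361 (21.1 TPM), and PTEN in SK-BR-3 (14.8 TPM) and AU-565 (15.2 TPM).

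**Figure D2:**
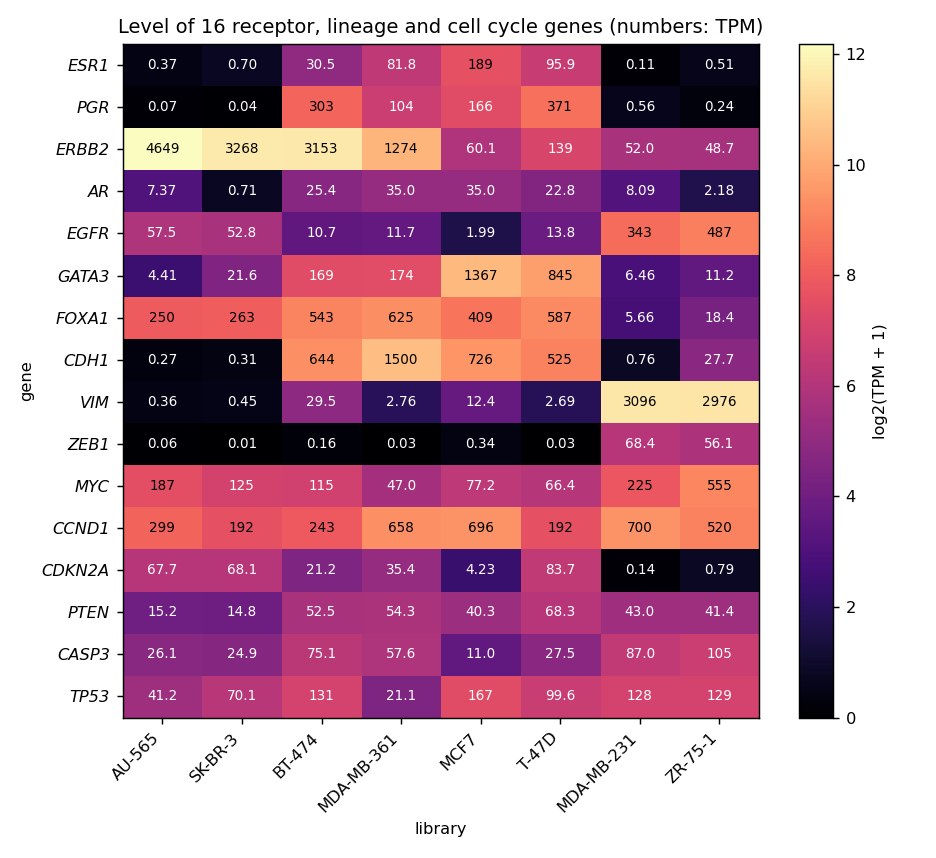
TPM of the 16 receptor, lineage and tumour genes in the 8 RNA libraries, with colour on a log2(TPM + 1) scale and the TPM printed in each cell. ERBB2 reached 4649 TPM in AU-565, ESR1 189 in MCF7 and VIM 3096 in MDA-MB-231.

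Estrogen receptor targets split the lines 4 against 4. The median of the 22 members considered was 2.66 higher on the log2 scale in MDA-MB-361, 2.64 in MCF7, 2.38 in T-47D and 1.63 in BT-474, with 13, 13, 12 and 10 members past the size rule upward. It was -3.32 in AU-565, -3.08 in SK-BR-3, -2.52 in MDA-MB-231 and -2.31 in the library labelled ZR-75-1, with 14, 11, 11 and 11 members past it downward. TFF1, a secreted trefoil peptide, stood at 1628 TPM in BT-474 and 0.355 in MDA-MB-231, and NPY1R, a neuropeptide receptor, at 4054 TPM in MCF7 and 0.358 in AU-565. Single members did not all follow the split, as TFF1 was lower in T-47D (14.6 TPM) than in the library labelled ZR-75-1 (22.1 TPM). XBP1, a fixed member, was listed at 0 in all 8 libraries, which does not show that it was silent, since the annotation used for counting is not known. All 8 calls held without any 1 library, while the median in BT-474 was 1.06 without AU-565 in the reference and that in SK-BR-3 was -1.81 without BT-474, MCF7 or MDA-MB-361. In the library labelled ZR-75-1 it was -1.15 without BT-474, -1.13 without MCF7, -1.28 without MDA-MB-361 and -1.36 without T-47D.

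The neighbours of ERBB2 on 17q12 were higher in BT-474 (median of 14 members 3.36, 12 past the size rule), AU-565 (2.30, 9 members) and SK-BR-3 (2.11, 8 members). They were lower in MCF7 (-1.74, 6 members), the library labelled ZR-75-1 (-1.32, 4 members) and MDA-MB-231 (-1.30, 4 members). GRB7, a signalling adaptor, stood at 614 TPM in AU-565, 536 in SK-BR-3, 465 in BT-474 and 236 in MDA-MB-361, against 2.48 in MDA-MB-231. GSDMB, a gasdermin, reached 633 TPM in SK-BR-3 and 467 in AU-565, and IKZF3, a lymphoid transcription factor, 88.9 in BT-474. In MDA-MB-231 the median was -0.82 without AU-565 or BT-474 and -0.75 without SK-BR-3, and in the library labelled ZR-75-1 it was -0.85 without AU-565 and -0.77 without BT-474 or SK-BR-3.

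Epithelial and mesenchymal genes parted MDA-MB-231 and the library labelled ZR-75-1 from the other 6. The mesenchymal median over 20 members was 5.78 in MDA-MB-231 (17 members past the size rule) and 5.28 in the library labelled ZR-75-1 (16 members). Epithelial adhesion genes were lower there, at -4.37 (14 of 18 members) and -3.59 (15 of 18), and luminal identity genes at -2.95 (12 of 17) and -2.02 (9 of 17). GRHL2, an epithelial transcription factor, stood at 0.0278 TPM in MDA-MB-231 and 2 in the library labelled ZR-75-1, against 162 in MCF7. The medians of epithelial adhesion (0.98, 3 of 18 members) and luminal identity (0.98, 5 of 17) were called higher in T-47D, with MUC1 at 891 TPM and AGR2 at 3200. The median of androgen receptor and apocrine genes was called lower in MCF7 (-1.12, 3 of 11 members).

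The median of 14 secreted luminal products was higher in MDA-MB-361 (3.69, 8 members past the size rule) and BT-474 (2.39, 6 members) and lower in MDA-MB-231 (-2.63, 6 members). SCGB2A2, mammaglobin, stood at 2295 TPM in MDA-MB-361 and 291 in BT-474, and MUCL1, a small mucin, at 475 and 2840. The library labelled ZR-75-1 had SCGB2A2 at 131 TPM, and MDA-MB-231 had it at 0.237.

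Inflammatory and antigen presentation genes were highest in MDA-MB-231. The median of the 20 NF-kB cytokine genes was 3.61 in MDA-MB-231 and 2.59 in the library labelled ZR-75-1, with 13 and 8 members past the size rule. IL6 stood at 35.4 and 6.52 TPM, CXCL8 at 121 and 53.9, and IL11 at 215 and 84.2. The median of interferon-stimulated genes was higher in both, at 1.89 and 1.08, with 6 and 4 of 26 members past the rule and BST2, which tethers viruses, at 236 and 129 TPM. The MHC class I presentation median was called higher in MDA-MB-231 (1.29, 5 of 15 members) and lower in BT-474 (-1.30, 3 members) and MCF7 (-1.24, 5 members), where PSMB8, an immunoproteasome subunit, stood at 9.23 and 0.214 TPM. MHC class II presentation was higher in MDA-MB-231 (3.75, 7 of 9 members), where CD74, its invariant chain, stood at 331 TPM.

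The median of AP-1 and immediate early genes was higher in the library labelled ZR-75-1 (2.02, 10 of 19 members) and MDA-MB-231 (1.93, 9 of 19) and lower in T-47D (-1.21, 4 of 19). FOSL1, an AP-1 subunit, stood at 763 and 414 TPM in the first of these libraries and in MDA-MB-231, and DUSP6, a feedback phosphatase of ERK signalling, at 426 and 369. Medians of lists with few members past the size rule were also called. That of hypoxia and glycolysis was higher in MDA-MB-231 (1.16, 2 of 25 members), with LDHA, lactate dehydrogenase A, at 3218 TPM. The cholesterol synthesis median was higher in BT-474 (0.75, 1 of 23 members), with HMGCS1 at 334 TPM. The cell cycle median was higher in T-47D (0.49, 0 of 30 members), with CCNB1 at 481 TPM. In MCF7, the median of p53 targets was higher (0.78, 0 of 25 members) and that of unfolded protein response genes lower (-0.60, 1 of 19), with HERPUD1 at 43.8 TPM.

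Among lists named after amplified regions, the median of the 17q23 list was higher in MCF7 (2.71, 10 of 16 members), BT-474 (1.54, 4 members) and MDA-MB-361 (1.33, 2 members). It was lower in SK-BR-3 (-2.35, 8 members) and AU-565 (-2.32, 10 members). BCAS3 stood at 610 TPM and PPM1D, a phosphatase that counters p53, at 218 TPM in MCF7. The 8q24 median was higher in AU-565 (0.82, 2 of 14 members) and SK-BR-3 (0.66, 4 members), with NDUFB9, a respiratory chain subunit, at 3445 and 2330 TPM, and lower in the library labelled ZR-75-1 (-1.08, 2 members) and MDA-MB-231 (-1.01, 1 member). MYC, a member of this list, went the other way in the library labelled ZR-75-1 (2.26 higher) and MDA-MB-231 (0.96 higher). The 20q13 median was higher in BT-474 (0.72, 5 of 21 members), with RAE1 at 560 TPM, and the 8p11 median lower in AU-565 (-1.60, 2 of 16 members), with FGFR1 at 0.174 TPM.

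Cancer-testis antigens, germline proteins expressed by tumours, were higher in AU-565 (3.75, 7 of 12 members), with CTAG2 at 373 TPM. SSX1 stood at 29.9 TPM in MDA-MB-231 and 47.8 in the library labelled ZR-75-1. CTAG2, MAGEA, SPANXB1, VCX and RFPL4A genes and HLA-DRB1 have near-identical copies or many alleles, so reads are hard to place among them and their values are uncertain. The median of replication-dependent histone mRNAs, which mostly lack a poly(A) tail, was higher in MDA-MB-361 (1.93) and MCF7 (1.52) and lower in the library labelled ZR-75-1 (-1.47), each with 3 of 10 members past the size rule, with H2AC6 at 57.3, 96.5 and 6.83 TPM.

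Fibroblast markers (5 considered) had medians from -0.05 to 0.86 and immune markers (5) from -0.20 to 0.80, with no call in any line. LAPTM5, an immune marker, nonetheless stood at 168 TPM in MDA-MB-231 and 68.0 in the library labelled ZR-75-1. Housekeeping genes (15) had medians from -0.17 to 0.37 and APOBEC3 enzymes (7) from -0.41 to 1.24, with no call. Over all lines, 49 list medians were called higher and 40 lower of 272, and 57 of the 89 calls held under every alternative. The nominal rate of the percentiles gives 2.72 calls for unlinked genes. Genes of a list vary together, so that number is no baseline for these lists.

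**Figure D3:**
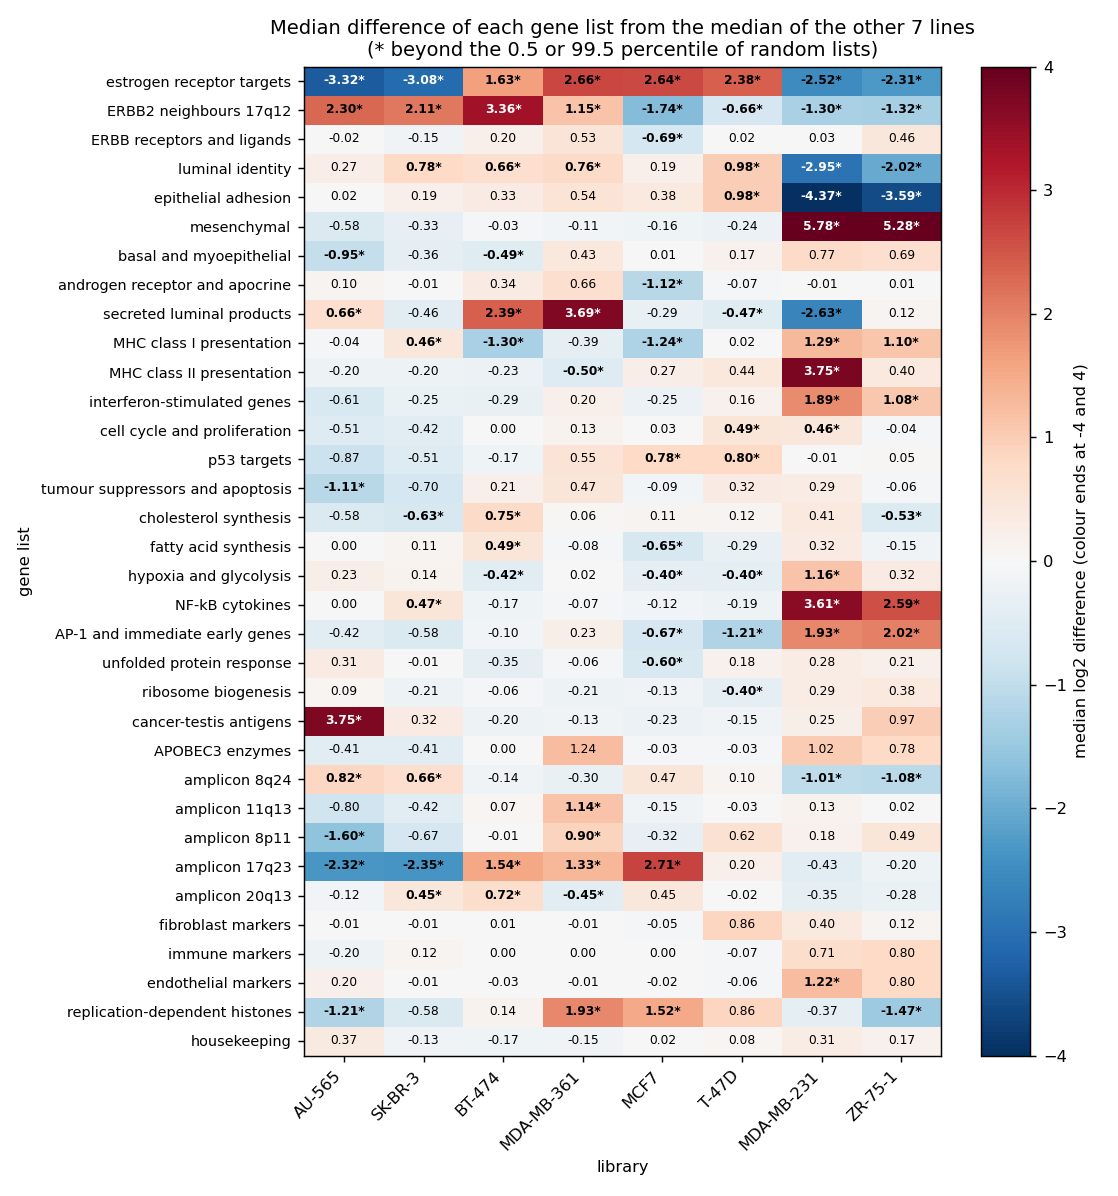
Median log2 difference of each of the 34 gene lists in each line from the median of the other 7 lines, with an asterisk on medians called beyond matched random lists. The mesenchymal medians are 5.78 in MDA-MB-231 and 5.28 in the library labelled ZR-75-1, and the 17q23 median is 2.71 in MCF7.

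The other 32 calls were each lost in at least 1 alternative, and several also with another pseudocount, filter, scaling or mean reference. Luminal identity in BT-474 (0.66) was lost without AU-565 (0.46) or without MDA-MB-231 or ZR-75-1 (0.36), and in MDA-MB-361 (0.76) without either of the latter libraries (0.61). In SK-BR-3 luminal identity (0.78) was lost without MCF7 or MDA-MB-231 (0.29). ERBB2 neighbours in MDA-MB-361 (1.15) were lost without MCF7 or T-47D (0.46), MDA-MB-231 (0.51) or ZR-75-1 (0.59), and in T-47D (-0.66) without AU-565 (-0.31), BT-474 (-0.30) or SK-BR-3 (-0.28). ERBB receptors and ligands in MCF7 (-0.69) were lost without MDA-MB-231 or ZR-75-1 (-0.45). Secreted luminal products in AU-565 (0.66) were lost without MCF7 (0.24) and turned to -0.030 without MDA-MB-231. In T-47D the same list (-0.47) was lost without AU-565 (-0.38) and without BT-474 or MDA-MB-361 (-0.31). Basal and myoepithelial genes in AU-565 (-0.95) were lost without MCF7 (-0.78). In BT-474 they (-0.49) were lost without MCF7 (-0.33), T-47D (-0.32), MDA-MB-361 (-0.26), and MDA-MB-231 or ZR-75-1 (-0.16). The 11q13 list in MDA-MB-361 (1.14) was lost without AU-565 (0.89), BT-474 (0.92), SK-BR-3 (0.85) or T-47D (0.91), its 8p11 list (0.90) without MCF7 (0.80) and its 20q13 list (-0.45) without SK-BR-3 (-0.35). The 20q13 list in SK-BR-3 (0.45) was lost with the mean as reference (0.37).

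MHC class I presentation in SK-BR-3 (0.46) was lost without BT-474, MCF7 or MDA-MB-361 (0.33), and in the library labelled ZR-75-1 (1.10) with a pseudocount of 5 (0.58). MHC class II presentation in MDA-MB-361 (-0.50) was lost without MCF7 or MDA-MB-231 (-0.29), ZR-75-1 (-0.30), and SK-BR-3 or T-47D (-0.36). NF-kB cytokines in SK-BR-3 (0.47) turned to -0.57 with the mean as reference. AP-1 and immediate early genes in MCF7 (-0.67) were lost without BT-474 (-0.37), MDA-MB-361 (-0.26), and MDA-MB-231 or ZR-75-1 (-0.18). Endothelial markers in MDA-MB-231 (1.22 over 8 members, with ESAM at 199 TPM) were lost without MCF7 (1.01), MDA-MB-361 (1.02) or T-47D (1.0). Histones in AU-565 (-1.21) were lost without MCF7 or MDA-MB-361 (-0.89) or T-47D (-0.92).

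Cell cycle genes in MDA-MB-231 (0.46) were lost without AU-565 (0.36), BT-474 or MCF7 (0.39), or ZR-75-1 (0.43). Cholesterol synthesis in SK-BR-3 (-0.63) was lost without MDA-MB-231 (-0.49). In the library labelled ZR-75-1 it (-0.53) was lost without BT-474 or T-47D (-0.26), MCF7 (-0.42) or MDA-MB-231 (-0.47). Fatty acid synthesis in BT-474 (0.49) was lost without MCF7 (0.41), T-47D (0.46) or ZR-75-1 (0.36), and in MCF7 (-0.65) without BT-474 (-0.43) or T-47D (-0.28). Hypoxia and glycolysis in BT-474 (-0.42) were lost without MDA-MB-231 (-0.32) or MDA-MB-361 (-0.33), and in MCF7 (-0.40) without MDA-MB-231 (-0.24). In T-47D they (-0.40) were lost without AU-565 (-0.07), BT-474 (-0.25), MDA-MB-231 (-0.09), MDA-MB-361 (-0.24), SK-BR-3 (-0.06) or ZR-75-1 (-0.19). In T-47D, p53 targets (0.80, with TP53I3 at 695 TPM) were lost without MDA-MB-231 (0.56) and ribosome biogenesis (-0.40, with NOP2 at 20.6 TPM) without ZR-75-1 (-0.33). Tumour suppressors and apoptosis genes in AU-565 (-1.11, with SMAD4 at 1.15 TPM) were lost without BT-474 (-0.61), MDA-MB-231 or ZR-75-1 (-0.75), MDA-MB-361 (-0.78), and MCF7 or T-47D (-1.0).

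The number of genes apart was highest in the library labelled ZR-75-1 (1037 higher, 480 lower) and MDA-MB-231 (1030 and 454). MDA-MB-361 had 795 higher and 169 lower, T-47D 531 and 200, MCF7 505 and 293, and BT-474 473 and 251. AU-565 (358 and 641) and SK-BR-3 (366 and 492) had more lower than higher. With the mean of the other lines as reference AU-565 kept this (351 and 512) and SK-BR-3 did not (375 and 364). By the median of ratios the libraries were shifted by -0.30 in AU-565, -0.17 in SK-BR-3, 0.19 in MDA-MB-361 and 0.10 in T-47D on the log2 scale, and rescaling removed these shifts. After it AU-565 had 522 higher and 483 lower and SK-BR-3 455 and 395, while MDA-MB-361 had 633 and 224.

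Several genes were abundant in some lines and low in the others. GPX1, a glutathione peroxidase, stood at 577 TPM in the library labelled ZR-75-1, 526 in MDA-MB-231, 418 in MDA-MB-361 and 368 in BT-474, against 0.269 in MCF7, 0.199 in SK-BR-3, 0.192 in T-47D and 0.1 in AU-565. GREB1, an estrogen-induced gene, stood at 527 TPM in MDA-MB-361, 368 in MCF7, and 169 in BT-474 and T-47D, against 0.128 in AU-565, 0.400 in SK-BR-3, 0.762 in MDA-MB-231 and 1.33 in the library labelled ZR-75-1. DHRS2, a short-chain dehydrogenase, stood at 4317 TPM in SK-BR-3, 3982 in AU-565, 829 in MDA-MB-361 and 509 in BT-474, against 14.6 or less in the other 4 libraries. MGP, an inhibitor of calcification, reached 4500 TPM in T-47D, against 0.930 in MDA-MB-231, 2.58 in SK-BR-3 and 8.23 in the library labelled ZR-75-1. Differences of such genes depended on which lines were in the reference, as for GPX1 in AU-565, at -8.39 with all 7 lines, -4.39 without BT-474, and -4.30 without MDA-MB-231, MDA-MB-361 or ZR-75-1.

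In AU-565, a HER2-positive line, the cancer-testis gene CTAG2 (8.47 higher), KRT4 (564 TPM, 8.35 higher), the calgranulins S100A9 (1104 TPM, 8.15 higher) and S100A8 (7.40), and SUSD2 (7.63) led. XAGE2, CPS1 (a urea cycle enzyme at 211 TPM), VGLL1, CRYAB, GSDMB and FBLN2 were between 7.39 and 6.84 higher. TMSB4X, an actin-binding peptide, was listed at 1.32 TPM against 1684 in the reference (-9.50). CDH1 (-8.70), IGFBP4 (-8.58), BASP1 (-7.91), PRSS23 (-7.35) and LGALS3 (-7.15) were lower too.

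SK-BR-3 shared much of this profile. S100A9 reached 2333 TPM (9.23 higher), H19, an imprinted noncoding RNA, 1565 TPM (8.40 higher), S100A8 584 TPM (8.19) and KRT4 461 TPM (8.06). GSDMB, CTAG2, SUSD2, FBLN2, SIGLEC6 and VGLL1 were between 7.28 and 6.69 higher, and MAGEA6 stood at 104 TPM. CDH1 (-8.65), IGFBP4 (-8.41), FADS1 (-7.30), LGALS3 (-6.95) and FADS2 (-6.82) were lower. FADS1 and FADS2, the fatty acid desaturases, were listed at 0.277 and 0.162 TPM.

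In BT-474, a HER2-positive line with estrogen receptor, TCN1 reached 11712 TPM against 1.80 in the reference (12.03 higher). MUCL1 was 8.56 higher, KIF1A, a neuronal kinesin, 7.49, and TFF1 6.71. ALOX15B, FAM83E, IKZF3, PLA2G2A and CST4 were between 6.32 and 6.07 higher. FXYD5 (-6.99), TMCO1 (-6.16), LGALS1 (-6.12), CBR1 (-6.05), FKBP10 (-5.90), GPX3 (-5.47) and IFITM2 (-5.33) were lower. MAGEA6 was listed at 0.129 TPM in BT-474 and 0.103 in MDA-MB-361.

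MDA-MB-361, which also expressed both receptors, had TCN1 at 5842 TPM (11.03 higher). PCSK1N, a proprotein convertase inhibitor, was 7.87 higher, CALML5 7.66, ALOX15B 7.40, CLCA2 7.35 and TFAP2B 7.04. FMOD, UGT3A2, TFF3 (1511 TPM) and TSPAN8 were between 6.89 and 6.6 higher. FXYD5 (-7.14), IFITM2 (-6.77), CYBA (-6.28), RPL39L (-6.05), TCIRG1 (-5.86), CBR1 (-5.83) and CPVL (-5.46) were lower.

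In MCF7, an estrogen receptor positive line, NPY1R was 9.37 higher than the reference, CXCL12, a chemokine, 8.55 (453 TPM), and TBX2, a transcription factor gene on 17q23, 8.02 (273 TPM). GFRA1, a GDNF receptor, was 7.91 higher, SULF2 7.71, NPNT 7.26, TFF1 6.69 and STC2 6.46. RAMP3, a receptor activity modifier, stood at 112 TPM and had a reference listed at 0. LDHB, lactate dehydrogenase B, was listed at 0.457 TPM against 569 (-8.61), and KRT7 at 11.8 against 2400 (-7.56). CTSZ (-7.34), CNN3 (-6.84), ALDH2 (-6.81), SLC40A1 (-6.18) and PSAT1 (-5.97) were lower.

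T-47D, also estrogen receptor positive, had SERPINA6, the cortisol carrier, at 2866 TPM (10.95 higher) and PIP, the prolactin-induced protein, at 2156 TPM (9.97 higher). CXCL12 (445 TPM) was 8.52 higher and STC2, a stanniocalcin, 8.22 (2175 TPM). OLFML3, GNG11, KRT23, PDZK1 and KCNK2 were between 7.85 and 7.07 higher, and OLFM1 stood at 290 TPM. LDHB was low here as well (0.245 TPM, -8.84). BASP1 (-7.92), S100A14 (-7.79), TES (-6.79), CYBA (-6.69) and MEST (-6.69) were lower.

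In MDA-MB-231, VIM (9.69 higher), COL8A1, a collagen chain (9.36), MSN (9.13), the metalloproteinases MMP1 (9.09) and MMP14 (8.90), and AXL, a receptor kinase (8.81), led. SPANXB1, SRGN, PLAT, SERPINE1 and NT5E (CD73, 705 TPM) were between 8.80 and 8.27 higher. CDH1 (-8.23), FXYD3 (-8.22), S100A14 (-8.11), RAB25 (-7.37), PREX1 (-7.24) and MAL2 (-6.99) were lower.

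Most of the 12 largest higher differences of the library labelled ZR-75-1 were in genes that also led in MDA-MB-231. VIM (9.63 higher), MSN (9.43), SPANXB1 (9.42), MMP1 and COL8A1 (9.32 each), AXL (9.18), MMP14 (8.49) and GPX1 were in both lists of 12. CCN2, a target of YAP and TAZ, stood at 2341 TPM (9.76 higher), KISS1 at 2170 TPM (9.51 higher), FOSL1 was 8.56 higher and ANKRD1 8.44. KRT7 (-7.34), PREX1 (-6.01) and GRB7 (-5.79) were lower, and C14orf132 was listed at 0.0928 TPM.

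AU-565 and SK-BR-3 were compared directly because catalogues list them as related lines, and they were grown in different media. The germline genes MAGEA1 (66.6 TPM in AU-565, 0.401 in SK-BR-3), VCX3A and PAGE5 were higher in AU-565, by 5.59, 5.52 and 5.25 on the log2 scale. RBP4, a retinol carrier (5.18), ADCY5 (4.95), AKR1B10 and MUCL1 (4.91 each), DCAF4L2 (4.87), VCX (4.77) and C11orf86 (4.48) followed. BASP1 (0.124 TPM against 107) and FBP1, a gluconeogenic enzyme (0.826 against 173), differed by -6.58 each and were higher in SK-BR-3. SIGLEC6 (-6.56), CNN3 (-5.61), SCIN (-5.38), RRAS2 (-5.16), GSTP1 (-5.10), PLAU (-5.04), CAPG (-4.73) and ANGPTL4 (-4.60) had the same direction. In all 92 genes were higher in AU-565 and 115 in SK-BR-3. Cancer-testis antigens (1.38) and secreted luminal products (0.46) were called higher in AU-565, and the 8p11 list (-0.66), NF-kB cytokines (-0.46) and the 20q13 list (-0.45) lower.

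MDA-MB-231 and the library labelled ZR-75-1 were compared after they were seen to be the closest pair. MHC class II genes were higher in MDA-MB-231 (median 3.58, 7 of 9 members), led by HLA-DRA (98.3 against 2.26 TPM, 4.93 higher), HLA-DRB1 (4.51), HLA-DPA1 (4.38) and CD74 (3.58). HLA-DPB1 was 3.84 higher, and 1.91 with a pseudocount of 5. The acute phase gene SAA1 (4.27) and complement C3 (3.74) were also higher, as were ALPP (4.61), VSTM2L (3.57) and VIPR1 (3.54). In the library labelled ZR-75-1, SCGB2A2 (131 against 0.237 TPM, -6.74), S100A9 (-6.63), S100A14 (-5.41), FXYD3 (-4.68), APOD (-4.49), AZGP1 (-4.43), PAEP (-4.39) and ALDH3B2 (-4.38) were higher, with RFPL4AL1 (-4.49) and RFPL4A (-4.27). In all 48 genes were higher in MDA-MB-231 and 76 in the other library. NF-kB cytokines (1.19), hypoxia and glycolysis (0.83), histones (0.66), MHC class I presentation (0.58), interferon-stimulated genes (0.47), cholesterol synthesis (0.46), cell cycle (0.38) and fatty acid synthesis (0.34) were called higher in MDA-MB-231. Secreted luminal products (-1.81), epithelial adhesion (-0.85), luminal identity (-0.49), the 8p11 list (-0.34) and ribosome biogenesis (-0.20) were called lower.

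**Figure D4:**
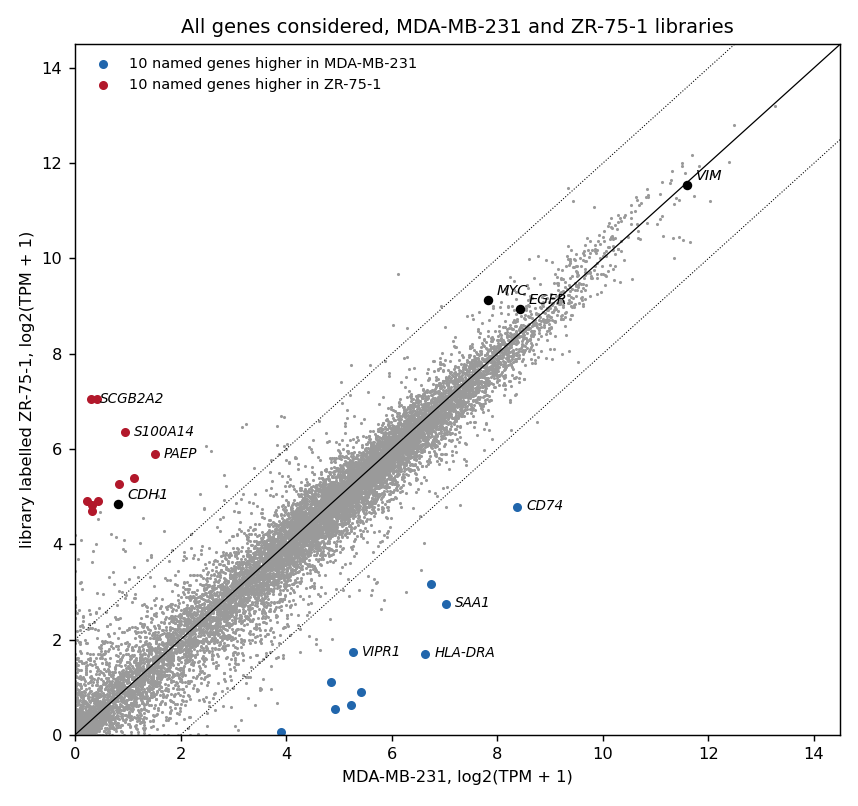
TPM of each gene in MDA-MB-231 (horizontal) and the library labelled ZR-75-1 (vertical), both on a log2(TPM + 1) scale, with dotted lines at differences of 2 and 10 genes named in each direction. The points lie close to the diagonal (r 0.976), and 124 genes lie past the dotted lines at 10 TPM or more.

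MYC and the ribosome biogenesis genes, which MYC is known to activate, rose together across lines. The change of the list was small, its mean log2(TPM + 1) running from 6.40 in T-47D to 6.93 in the library labelled ZR-75-1. MYC ran from 5.59 in MDA-MB-361 to 9.12 in the library labelled ZR-75-1. Over 7 values Pearson's r was 0.942 (exact permutation p 0.00139, adjusted 0.00417 over the 3 relations tested) and Spearman's rho 0.964 (exact permutation p 0.00278, adjusted 0.00833). Without MDA-MB-361 and the library labelled ZR-75-1, the farthest values of MYC, r was 0.950. With MDA-MB-231 and the library labelled ZR-75-1 also averaged, which left 6 values, r was 0.921 (exact permutation p 0.0111). Within the 4 lines grown in DMEM, a split added after the data were seen, r was 0.971 (exact permutation p 0.0417, the smallest that 4 values allow). Spearman's rho there was 1 (exact permutation p 0.0833).

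NLRC5, the activator of MHC class I genes, was compared with the other class I genes. NLRC5 with MHC class I presentation had r 0.770 (exact permutation p 0.0462, adjusted 0.0693) and rho 0.821 (exact permutation p 0.0341, adjusted 0.0512), and so did not pass after adjustment. Without MCF7 and MDA-MB-231, the farthest values, r was 0.387, so the relation rested on them. The raw p was also above 0.05 without BT-474 (r 0.814), MCF7 (0.660), MDA-MB-231 (0.613), T-47D (0.811) or ZR-75-1 (0.730). AR had r 0.161 with the androgen receptor and apocrine genes (exact permutation p 0.714, adjusted 0.714) and rho 0.107 (exact permutation p 0.840, adjusted 0.840), and r 0.329 without its farthest values. Of the 7 relations fixed, those of ESR1, ERBB2, ZEB1 and GATA3 with their lists were not tested, because the largest gap spanned 0.589, 0.507, 0.892 and 0.506 of the range of these genes. The labels give no batch. Within the 4 lines in DMEM, NLRC5 with MHC class I presentation had r 0.934 (exact permutation p 0.0833), AR had no value because its largest gap spanned 0.776 of the range, and the other media held too few lines.

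Neighbouring genes differed together in 117 runs, 71 higher and 46 lower, called on window medians and not on the size rule. Around ERBB2 on chromosome 17, runs were higher in BT-474 (35760887 to 40284136, 70 genes, median 2.29), SK-BR-3 (38800441 to 40357643, 36 genes, 1.61), AU-565 (38765691 to 40357643, 37 genes, 1.53) and MDA-MB-361 (39173453 to 40054408, 21 genes, 0.42). A run takes in all genes of its called windows. In MDA-MB-361 the median over the run was far below the bound of 1.70 that a window had to pass there. Farther along, at 17q23, MCF7 had a higher run (59170859 to 63498373, 41 genes, 1.63) and BT-474 another (58352500 to 60666280, 32 genes, 1.30). AU-565 (58345178 to 62693597, 47 genes, -1.82) and SK-BR-3 (56887909 to 62693597, 61 genes, -1.65) had lower runs over the same region.

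**Figure D5:**
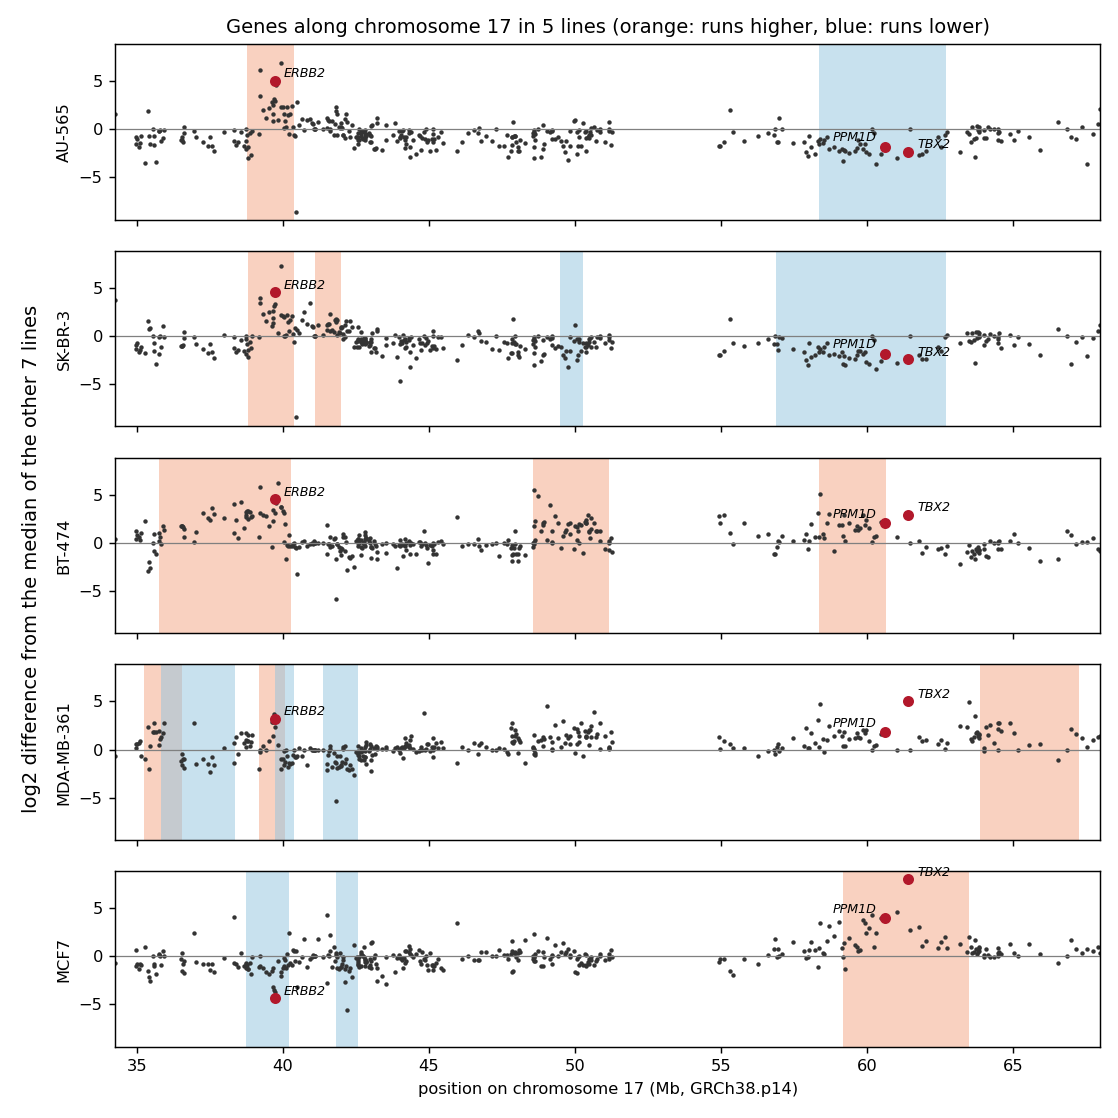
Log2 difference from the median of the other 7 lines for each gene along chromosome 17 (position in Mb, GRCh38) in AU-565, SK-BR-3, BT-474, MDA-MB-361 and MCF7, with called runs shaded. BT-474 has a run of 70 genes with a median of 2.29 around ERBB2, and AU-565 a run of 47 genes with a median of -1.82 farther along.

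On chromosome 8, runs were higher in SK-BR-3 (110937690 to 125022283, 51 genes, 1.22) and AU-565 (119557086 to 125022283, 35 genes, 1.16), and lower in AU-565 (91070344 to 98036724, 34 genes, -1.87) and SK-BR-3 (90993802 to 98093609, 39 genes, -1.72). Both lines had a lower run of zinc finger genes on chromosome 19, ending at CCNE1, with medians of -2.10 and -1.72. MCF7 had a higher run on chromosome 1 (112674439 to 116571026, 34 genes, 1.52). Histone genes on chromosome 6 formed higher runs in MDA-MB-361 (26020451 to 26453415, 30 genes, 1.91) and MCF7 (25962802 to 26415208, 30 genes, 1.53), and a lower run in the library labelled ZR-75-1 (26020451 to 26394874, 27 genes, -1.34). In T-47D, protocadherin genes on chromosome 5 (140726159 to 141512975, 33 genes) had a median of 1.60, and chromosome 12 held a lower run (6724046 to 8949645, 45 genes, -0.98). Of the 7 runs of the library labelled ZR-75-1, 7 overlapped a run of MDA-MB-231 in the same direction. Of the runs of AU-565, 13 of 17 overlapped one of SK-BR-3, and 13 of the 26 of SK-BR-3 one of AU-565. How many would overlap by chance was not tested.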

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

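The averaging of MDA-MB-231 with the library labelled ZR-75-1 and all settings for that pair were chosen after the data were seen, and the other alternatives were planned. Of 318 results for a named gene, 282 kept their direction and their side of the size rule in every alternative run for them and 0 reversed. The 278 in a line had 15 settings and the 40 in a pair 5. Among these settings, no filter and the filter of 5 TPM could not change a gene call, since the size rule asks for 10 TPM. Many named genes were picked as the largest of their line, at 5.33 or more in size, so most settings could hardly move them past the rule. In simulation 3 of 100 lists of unlinked genes were called, more often than the nominal rate. Of 89 list calls, 57 were kept and 2 reversed: NF-kB cytokines in SK-BR-3 were at -0.57 with the mean as reference, and secreted luminal products in AU-565 ranged from -0.030 (without MDA-MB-231) to 1.70 over the leave-one-out references. The 2 closest pairs kept their ranks in all settings. A pseudocount of 5, which shrinks differences of genes at low TPM, gave fewer genes apart: AU-565 228 higher and 315 lower, BT-474 289 and 127, MCF7 301 and 154, MDA-MB-361 455 and 82, SK-BR-3 235 and 246, T-47D 295 and 110, ZR-75-1 676 and 280, and MDA-MB-231 296 lower. It gave 48 and 48 genes between AU-565 and SK-BR-3 and 24 and 40 between MDA-MB-231 and the library labelled ZR-75-1. With the mean as reference 70 lists were called lower. Windows of 9 genes gave 32 higher runs, windows of 25 genes 113 higher and 110 lower, and a pseudocount of 5 gave 73 lower runs. The cause of these changes in lists and runs was not tested. NLRC5 with MHC class I presentation had r 0.728 after rescaling, 0.704 with the median over members and 0.677 with MDA-MB-231 and ZR-75-1 averaged, each with an exact permutation p above 0.05, and 0.613 to 0.848 over the leave-one-out values, and the cause was not tested. The relation of AR with both pairs averaged, and those of AR and MYC without MDA-MB-231, fell into separate clusters and gave no value. Removal of mitochondrial genes was not run, since none of the fixed list were in the table. No paired analysis was possible because each line has 1 RNA library. At 10 TPM depth was a median of at least 365 reads in every library, and lower genes near 0 TPM rested on few reads, such as 2 for GPX1 in AU-565 and 1 for RAB25 in MDA-MB-231, so their differences are imprecise.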

Other observations

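The tests of explanations in this part were chosen only after the result was seen, while the rescaling, the mean reference and the gene lists were fixed before. Across the lines, 107 genes stood at 100 TPM or more in at least 2 lines and below 1 TPM in at least 2 others. They include enzymes such as GPX1, LDHB, FADS1, FADS2 and GSTP1, the adhesion gene CDH1, and mesenchymal genes such as VIM, AXL and CAV1. APOBEC3B, a cytidine deaminase, was listed at 0 in AU-565 and 0.0241 TPM in SK-BR-3, against 68.4 in BT-474, 49.3 in MDA-MB-231 and 8.48 in MCF7. MTAP, the neighbour of CDKN2A, was listed at 0.0305 TPM in MDA-MB-231, 0.237 in MCF7 and 1.13 in the library labelled ZR-75-1, against 30.4 in AU-565.

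ASNS and CHAC1, chosen after their values were seen, were the members of the unfolded protein response list past the size rule in the library labelled ZR-75-1. ASNS, asparagine synthetase, stood at 811 TPM there against 68.0 in MDA-MB-231 and 91.5 in SK-BR-3, and CHAC1, a glutathione-degrading enzyme, at 168 TPM against 32.0 and 10.6. The list itself was not called there (median 0.21, 2 of 19 members).

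The library labelled ZR-75-1 lay close to MDA-MB-231. Whether these labels were exchanged cannot be decided by the mesenchymal median, which was 5.78 in the library labelled MDA-MB-231 and 5.28 in that labelled ZR-75-1. It would be high under either label. Some values go with MDA-MB-231 RNA as most of the library labelled ZR-75-1. There, 35 genes specific to MDA-MB-231 stood at a median of 81.6% of the MDA-MB-231 level (quartiles 52.4% to 108%). Another 28 genes, of the other 6 lines and lacking in MDA-MB-231, stood at 4.87% of the level of those lines (quartiles 3.12% to 6.8%). The MHC class II genes cannot decide whether RNA of the sequenced MDA-MB-231 library's profile makes up most of the library labelled ZR-75-1. They were picked for this after they were seen to differ, and they vary together, so they are not 7 separate checks. These 7 genes stood at a median of 2.30% of their level in MDA-MB-231 (quartiles 1.82% to 6.29%), and 48 genes in all were at least 4-fold lower. In the other direction 22 genes such as SCGB2A2, S100A9 and AZGP1 stood at 10 TPM or more and below 1 TPM in MDA-MB-231. These sets were taken by their difference between the libraries, while the 35 specific genes were not, so no conclusion is drawn. Material of a different MDA-MB-231 culture and ZR-75-1 cells in a state close to MDA-MB-231 cannot be told apart with 124 genes apart, since no other library of either line was used here. All 7 runs of neighbouring genes of the library labelled ZR-75-1 overlapped runs of MDA-MB-231 in the same direction, which was not used to choose between these explanations. Other explanations were not tested.

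Of the 107 genes abundant in some lines and near 0 in others, 56 were abundant only in MDA-MB-231 and the library labelled ZR-75-1 and 13 only in AU-565 and SK-BR-3, so each of these close pairs counted as 2 lines. For the set, loss of a chromosome segment that spans the nearest genes is argued against as the cause. These neighbours had a median difference of -0.40 (quartiles -0.83 to 0.05, and a median of -0.32 for the other 38 genes) against -7.51 for the genes themselves. Neighbours that were among the 107 were left out, as FADS1 and FADS2 were for each other, and neighbours at low TPM could fall little. Both can pull the median toward 0, so joint loss of adjacent genes of the set was not tested. In MAGEA3 (-3.10) and SDC2 (-2.42) the neighbours were down at least 4-fold too. For the 13 genes with pseudogenes in the table, reads assigned to pseudogenes are argued against, since these held at most 0.132% of the gene's level. Silencing, small deletions and variants against the reference stay open, and no biological explanation was tested.

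More genes were lower than higher in AU-565 and SK-BR-3, in SK-BR-3 not with the mean as reference (375 higher, 364 lower). After median-of-ratios rescaling 51.9% of genes apart were higher in AU-565, against 35.8% before, and 53.5% against 42.7% in SK-BR-3; since rescaling centres the median gene, the scale of TPM and a real excess of lower genes cannot be told apart. MDA-MB-361 kept more higher genes, at 73.9% after rescaling and 82.5% before. The 10 most abundant genes of each library are argued against as the whole cause, since the log2 shift of AU-565 was -0.25 without them and -0.30 with them. No biological explanation was tested.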
